A study of Arabidopsis thaliana with 24 samples.

How the data were processed

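RNA of whole 5-day-old Arabidopsis thaliana seedlings was profiled in 24 libraries from wild-type Col-0 and from a pair of transgenic lines that express YFP-ARF19, unchanged or with the K962A substitution, from the UBQ10 promoter. Each was kept 2 h in liquid medium with ethanol (mock) or 10 µM IAA, and there were 4 libraries per group. Per the labels, seedlings grew at 22 °C under continuous light, RNA was extracted with a Qiagen RNeasy Plant kit and ribosomal RNA was removed with Ribo-Zero Gold. The submitters' processing notes name STAR 2.0.4b, Subread, featureCounts 1.45 and the TAIR10 genome without giving the role of each. The strand setting of the counting is not given in the sources used here, so sense reads cannot be told from antisense or overlapping ones.

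Values for 33602 genes were read per library. The first value per gene holds raw counts, which the authors made and which are whole numbers that differ in sum between libraries. The deposited CPM values are counts scaled to the total of the library, and the deposited RPKM values are that CPM per kilobase of gene length, per the file headers. Tests used the counts; the deposited CPM and RPKM were read only for checks of unit. Of the gene identifiers 32835 were in the TAIR10.1 annotation, and 32834 had an overlapping span; 1024 genes had no read in any library. Every per-sample table was assigned to its group from the labels and none was left over.

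Depth ranged from 15.0 to 49.7 M counts with a median of 38.0 M. Plastid genes (133) held 28.2 to 39.3% of the counts and the 4 nuclear ribosomal RNA genes 0.00414 to 2.02%; 146 mitochondrial genes were counted too. Between replicate libraries of a group, the chi-square per degree of freedom of the counts was 9.98 to 94.4 over 36 pairs, where counting noise alone gives about 1; a few abundant genes can carry this average.

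Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 6 groups with a minimum count of 10, which left 22052, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 24 libraries with 1 coefficient per group. The 9 contrasts were IAA against mock in each line, each pair of lines in mock, and each pair of IAA responses as a difference of differences. P-values were adjusted over the tested genes of each contrast by Benjamini-Hochberg and genes were called at an adjusted p under 0.05. Counts of at least 2-fold changes used an absolute log2 fold change of at least 1. CPM values in the text are the TMM-scaled ones computed here.

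The 22 gene lists (357 genes) were written from general knowledge of Arabidopsis genes before the data were examined. Each was tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the 22 lists, and its members were also adjusted over the list alone. The canonical score is the mean log2 CPM (prior count 2) of 27 measured auxin-induced genes per library. Nearly all of these genes also belong to the Aux/IAA, GH3, lateral root initiation or ethylene lists. Results of the canonical list and of those lists are therefore not independent. The common response holds the genes called in the mean IAA effect of the 3 lines with an absolute log2 change of at least 1, a choice that treats the lines alike, and its score is the mean log2 CPM over these genes with the sign of that effect. Scores were compared by exact permutation of library labels, two-sided, with 70 relabellings for a pair of groups and 4900 for a difference of responses, in which lines were relabelled within each treatment, so that any line difference shared by both treatments widens the reference values; p-values were adjusted over 12 tests per score. Mock differences along the IAA response used IAA calls of the line outside the comparison, so that no library served in both.

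Genes named in the text were chosen by a rule set before the data were examined: ARF19 in every comparison; in each contrast up to 8 genes with the highest and 8 with the lowest fold change among called genes with a mean of at least 5 CPM and, for a pair of groups, non-overlapping libraries; and for each list up to 4 called members with the largest change, or the 2 most abundant members as values where fewer than 2 were called. A gene named in one comparison may have its values given in another. Genes named outside this rule are marked where they appear.

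The procedure was tested on simulated data, counts drawn with the estimated dispersion of each gene and with known changes in genes of at least 5 CPM. In the Col-0 IAA comparison it recovered 61.2% of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold changes with 9 false calls among 21796 genes. For K962A against Col-0 in mock the shares were 79.1%, 98.5% and 100% with 5 false calls among 21761. For the difference of responses between K962A and Col-0 they were 23.9%, 86.6% and 95.5% with 10 among 21763. All simulated groups shared 1 dispersion per gene. The simulation therefore lacks the wider spread of the real K962A mock libraries, and its false calls do not cover that spread.

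Alternatives tried were DESeq2 size factors in edgeR, DESeq2 1.42.0 with its own filter, no filter on low counts, a filter of 10 CPM in 4 libraries, leaving out organelle and ribosomal RNA genes, fitting only the groups of a contrast, the replicate number as a block, each library left out in turn, a prior count of 0.5, and a stricter threshold of 0.01. Leaving out the libraries under 20 M counts was added after seeing the data. The replicate numbers did not pair libraries across groups, so no pairing was used in the tests. Other splits of the same libraries were refitted to see how many genes they call, with all 35 splits for a pair of groups and 50 drawn splits for a difference of responses. Values were handled with the R package data.table, version 1.17.8.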

Results

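Transcript levels were measured in whole 5-day-old Arabidopsis thaliana seedlings of 3 lines in the Columbia accession. Col-0 is the wild type. The other lines are Col-0 plants that carry the AUXIN RESPONSE FACTOR 19 protein fused to yellow fluorescent protein under the constitutive UBQ10 promoter. The protein is either unchanged (YFP-ARF19) or carries the K962A substitution (YFP-ARF19 K962A), which replaces a lysine of the carboxy-terminal PB1 domain, through which ARF proteins multimerise, with alanine. Seedlings of each line were kept for 2 h in liquid medium with ethanol (mock) or 10 µM indole-3-acetic acid (IAA), the main natural auxin. The 6 groups held 4 libraries each, 24 in all. Total counts per library ranged from 15.0 to 49.7 M with a median of 38.0 M. Mean depth was 32.1 M in Col-0 mock, 39.6 in Col-0 IAA, 27.2 in YFP-ARF19 mock, 32.1 in YFP-ARF19 IAA, 43.8 in K962A mock and 38.1 in K962A IAA. Libraries under 20 M numbered 2 (Col-0 mock replicate 1 at 15.0 M and YFP-ARF19 mock replicate 3 at 17.8 M). The labels state that the treatments were repeated in quadruplicate but not that the 4 came from separate cultures, so all p-values measure the spread between these samples. Values after ± are approximate standard errors of log2 fold changes unless another error is named. They are the absolute log2 fold change over the square root of the quasi-likelihood F statistic. They thus rest on a dispersion estimated over all 24 libraries, with 4 libraries per group. For score differences the standard error was computed from the variance within each group.

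ARF19 (AT1G19220, TAIR10 chromosome 1, 6628068 to 6633087, minus strand) is the gene carried by the transgenes, and it was read first in every library. In Col-0 it had 53.7 ± 6.72 counts scaled to library size and a common total (CPM, SD, n = 4) in mock and 78.7 ± 4.60 with IAA. In the YFP-ARF19 line it had 979 ± 192 CPM in mock and 3126 ± 322 with IAA, and in the K962A line 1519 ± 161 in mock and 2984 ± 349 with IAA (SD, n = 4 each). Every transgenic library lay above every Col-0 library, the lowest transgenic value being 810 CPM and the highest Col-0 value 83.3 CPM. Gene counts do not separate transgene transcripts from those of the endogenous gene. In mock, ARF19 reads were higher than in Col-0 by 4.19 ± 0.15 on the log2 scale in the YFP-ARF19 line (edgeR, Benjamini-Hochberg adjusted p = 5.1e-16) and by 4.82 ± 0.15 in the K962A line (adjusted p = 3.4e-17). The K962A line exceeded the YFP-ARF19 line in mock by 0.63 ± 0.13 (edgeR, Benjamini-Hochberg adjusted p = 0.000591). With IAA, ARF19 reads rose by 0.55 ± 0.13 in Col-0 (adjusted p = 0.00217), 1.68 ± 0.13 in the YFP-ARF19 line (2.3e-10) and 0.97 ± 0.13 in the K962A line (1.0e-06; edgeR, Benjamini-Hochberg). The rise was larger in the YFP-ARF19 line than in Col-0 by 1.12 ± 0.19 (adjusted p = 0.00188) and smaller in the K962A line than in the YFP-ARF19 line, with a difference of -0.70 ± 0.19 (0.00961; edgeR, Benjamini-Hochberg). That between the K962A line and Col-0, 0.42 ± 0.19, was not called (edgeR, Benjamini-Hochberg adjusted p = 0.127). This difference was called in 1 refit, without K962A IAA replicate 4 (0.55, adjusted p = 0.0491).

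**Figure D1:**
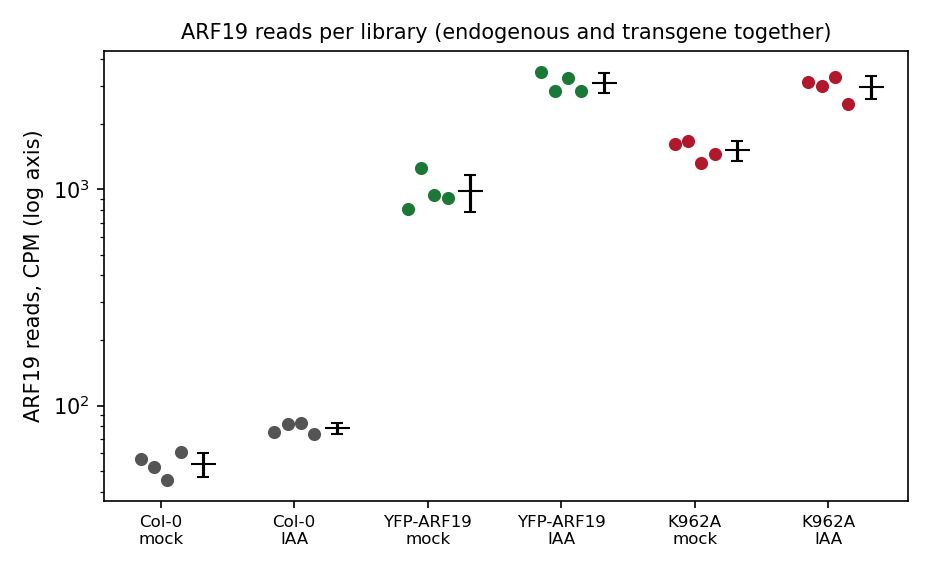
ARF19 reads in CPM (log axis) in each of the 24 libraries, by line and treatment, with group means. Col-0 libraries lie at or below 83.3 CPM and all transgenic libraries at or above 810 CPM.

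The first principal component of the 24 libraries held 48.7% of the variance and the second 18.9%. The 4 K962A mock libraries were spread more widely in auxin-induced transcripts than any other group. The mean log2 CPM of 27 canonical auxin-induced genes was 4.42, 3.43, 3.69 and 2.67 in replicates 1 to 4, a mean of 3.55 ± 0.72 (SD, n = 4), against SDs of 0.04 to 0.13 in the other 5 groups.

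**Figure D2:**
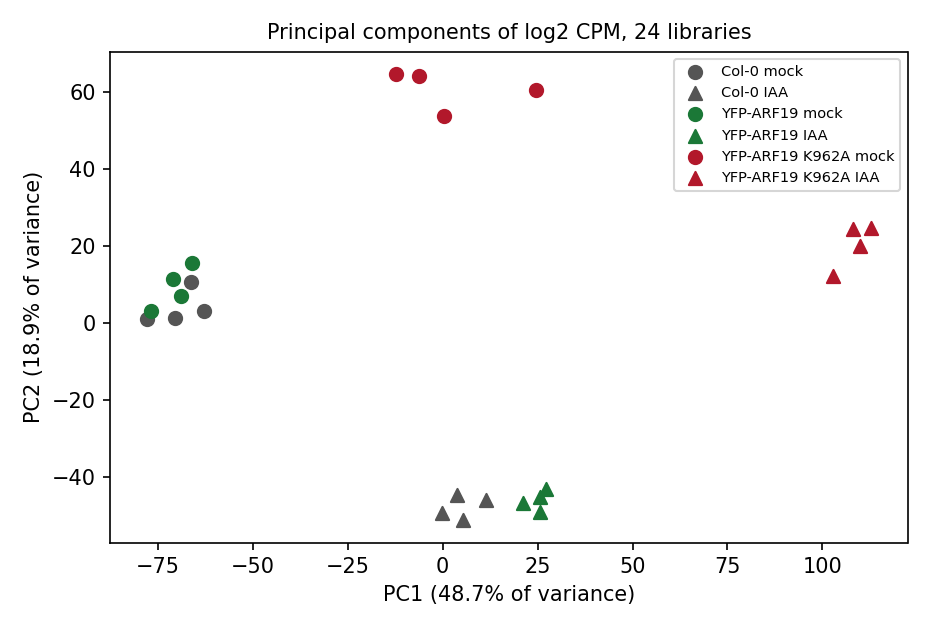
First (48.7% of variance) and second (18.9%) principal components of log2 CPM over the tested genes, 1 point per library, coloured by line and shaped by treatment. Points are single libraries and no error is drawn.

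The first comparison asked how wild-type seedlings responded to 2 h of IAA. In Col-0, GH3.2 and GH3.3, which encode enzymes that conjugate IAA to amino acids, rose by 5.19 ± 0.37 and 5.09 ± 0.46 on the log2 scale, GH3.3 (AT2G23170, chromosome 2, 9863855 to 9866562) from 64.8 to 2208 CPM. LBD29, a transcription factor gene of lateral root initiation, rose by 4.96 ± 0.17, and the Aux/IAA repressor genes IAA5 and IAA29 by 4.23 ± 0.45 and 3.47 ± 0.29. CYP735A2 (AT1G67110, chromosome 1, 25061731 to 25065446), a cytokinin trans-hydroxylase, was lower at -4.55 ± 0.41, from 12.6 to 0.5 CPM, as were the monolignol glucosyltransferase gene UGT72E2 (-4.53 ± 0.17) and MYB34, a regulator of indole glucosinolate synthesis (-3.46 ± 0.34). Among the 22052 genes tested, 5862 were called at an adjusted p under 0.05, 3147 higher and 2715 lower, 2104 of them at least 2-fold. Adjusted p-values were 1.8e-10 for GH3.2, 1.2e-16 for LBD29 and 6.2e-09 for CYP735A2 (edgeR, Benjamini-Hochberg).

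Of 27 measured canonical auxin-induced genes, 26 rose in Col-0 and none fell (26 adjusted over the list alone, camera adjusted p = 5.2e-30, and 0.0339 with an estimated correlation). Aux/IAA genes rose in 20 of 28 cases and fell in 2 (21 and 2 adjusted over the list alone, camera adjusted p = 3.0e-11, adjusted p = 0.0720 with an estimated correlation). GH3 genes rose in 6 of 7 (6 over the list alone, 1.9e-06, adjusted p = 0.0731 with an estimated correlation). SAUR genes, small auxin-up RNAs linked to cell expansion, rose in 27 of 46 and fell in 7 (27 and 7 over the list alone, 4.1e-09, adjusted p = 0.0546 with an estimated correlation). SAUR10 rose by 3.09 ± 0.22 and SAUR28 by 3.03 ± 0.24; the SAUR19 to SAUR24 and SAUR61 to SAUR68 clusters are near-identical copies that may share reads. Lateral root initiation genes rose in 12 of 18 and fell in 1 (12 and 2 over the list alone, camera adjusted p = 4.8e-08, 0.0339 with an estimated correlation), with MAKR4 at 3.97 ± 0.14 and LBD33 at 3.82 ± 0.24. Auxin transport genes rose in 10 of 20 and fell in 4 (10 and 4 over the list alone, 0.00519, adjusted p = 0.0546 with an estimated correlation). The PIN-LIKES gene PILS5 and the kinase gene PID rose by 2.00 ± 0.13 and 1.94 ± 0.20, and PIN5 was at -1.70 ± 0.37. Auxin synthesis and oxidation genes fell in 10 of 16 and rose in 2 (11 and 2 over the list alone, camera adjusted p = 0.000381, 0.0455 with an estimated correlation), including CYP79B2 (-2.19 ± 0.19) and CYP79B3 (-2.10 ± 0.27), which convert tryptophan to indole-3-acetaldoxime. Among 20 ARF and auxin receptor genes 2 rose and 5 fell (4 and 6 over the list alone, camera adjusted p = 0.718), the largest changes being ARF5 at 0.67 ± 0.11 and ARF18 at -0.49 ± 0.14, a call lost when only the groups of the contrast were fitted (adjusted p = 0.0842).

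Ethylene genes rose in 8 of 20 and fell in 2 in Col-0 (8 and 3 over the list alone, camera adjusted p = 0.00417, adjusted p = 0.234 with an estimated correlation). The genes ACS11, ACS4 and ACS6, which encode 1-aminocyclopropane-1-carboxylate synthases, the enzymes that commit to ethylene synthesis, rose by 3.45 ± 0.27, 3.05 ± 0.19 and 2.60 ± 0.17. Cytokinin genes fell in 11 of 15 and rose in 2 (11 and 3 over the list alone, 0.00136, adjusted p = 0.111 with an estimated correlation), among them the type-A response regulators ARR6 (-2.25 ± 0.29) and ARR5 (-1.78 ± 0.31). Root hair genes fell in 7 of 8 (7 over the list alone, 1.9e-06, 0.0339 with an estimated correlation), with COW1 at -2.03 ± 0.12 and RSL4 at -1.91 ± 0.32. Other root markers fell in 8 of 13 (8 over the list alone, 0.00417, adjusted p = 0.111 with an estimated correlation), with the nitrate transporter gene NRT2.1 at -2.10 ± 0.18. Defence and jasmonate genes rose in 8 of 20 and fell in 1 (8 and 1 over the list alone, 0.0231, adjusted p = 0.419 with an estimated correlation), led by the transcription factor genes WRKY40 (3.12 ± 0.27) and WRKY33 (2.58 ± 0.17).

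The remaining lists were not called as sets in Col-0. Brassinosteroid and gibberellin genes rose in 4 of 11 and fell in 3 (camera adjusted p = 0.244), with the gibberellin 2-oxidase gene GA2OX6 at 1.75 ± 0.24. Expansin and XTH cell wall genes rose in 9 of 23 and fell in 7 (0.396; median -0.08, mean 0.20), with XTH22 at 3.27 ± 0.19 and EXPA17 at -2.38 ± 0.46. Hypoxia genes rose in 4 of 12 and fell in 6 (0.941; median -0.28, mean 0.12), with PDC1 at 2.49 ± 0.19 and HRA1 at -1.75 ± 0.25. Cell cycle genes fell in 3 of 14 (camera adjusted p = 0.264), heat genes rose in 2 of 7 (0.0833), and abscisic acid and cold genes rose in 1 of 6 (0.259). Circadian genes rose in 6 of 13 and fell in 1 (0.163), and flavonoid genes rose in 1 of 9 and fell in 2 (0.264). None of 17 photosynthesis genes was called by edgeR, over all genes or over the list alone (camera adjusted p = 0.259): RBCS1A was at -0.11 ± 0.12 and LHCB1.3 at -0.25 ± 0.19.

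The next comparison asked how IAA acted in seedlings with the unchanged YFP-ARF19 fusion. In that line LBD29 rose by 5.76 ± 0.17, GH3.2 and GH3.3 by 5.65 ± 0.37 and 5.58 ± 0.47, and IAA30 and IAA29 by 5.57 ± 0.46 and 5.36 ± 0.32. ACS8 and ACS4 rose by 4.38 ± 0.49 and 4.28 ± 0.20, and the cytokinin oxidase genes CKX3 and CKX6, which encode enzymes that degrade cytokinin, by 3.02 ± 0.27 and 2.45 ± 0.13. Among genes that fell were CYP735A2 (-5.74 ± 0.49), UGT72E2 (-4.75 ± 0.18), MYB34 (-3.92 ± 0.36) and the auxin synthesis genes YUC6 (-3.60 ± 0.19) and YUC8 (-2.65 ± 0.21), which encode flavin monooxygenases that make IAA. There were 6820 called genes, 3644 higher and 3176 lower, 2758 of them at least 2-fold. Adjusted p-values were 5.0e-18 for LBD29, 4.7e-07 for ACS8 and 2.0e-13 for YUC6 (edgeR, Benjamini-Hochberg).

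All 27 canonical genes rose in the YFP-ARF19 line (27 over the list alone, camera adjusted p = 8.5e-33, 0.0156 with an estimated correlation). Aux/IAA genes rose in 21 of 28 and fell in 2 (21 and 3 over the list alone, 3.7e-14, 0.0370 with an estimated correlation). SAUR genes rose in 31 of 46 and fell in 7 (34 and 7 over the list alone, 4.7e-13, 0.0166 with an estimated correlation). Lateral root initiation genes rose in 14 of 18 and fell in 2 (14 and 2 over the list alone, 1.3e-09, 0.0156 with an estimated correlation). Ethylene genes rose in 15 of 20 and fell in 1 (16 and 2 over the list alone, camera adjusted p = 2.2e-07, 0.0357 with an estimated correlation). Genes of auxin synthesis and oxidation fell in 11 of 16 and rose in 2 (11 and 2 over the list alone, 1.2e-05, 0.0156 with an estimated correlation). Root hair genes fell in 7 of 8 (8 over the list alone, 2.7e-06, 0.0156 with an estimated correlation). Auxin transport genes rose in 10 of 20 and fell in 4 (11 and 4 over the list alone, 0.00564, 0.0429 with an estimated correlation), PID by 2.73 ± 0.20 and the influx carrier gene LAX2 by 1.88 ± 0.18. GH3 genes rose in 5 of 7 (6 over the list alone, 3.7e-06, adjusted p = 0.0683 with an estimated correlation). Cytokinin genes fell in 11 of 15 and rose in 4 (11 and 4 over the list alone, 0.00905, adjusted p = 0.191 with an estimated correlation). Root markers fell in 7 of 13 (9 over the list alone, 0.000617, adjusted p = 0.0610 with an estimated correlation). Defence and jasmonate genes rose in 8 of 20 and fell in 1 (9 and 1 over the list alone, 0.00106, adjusted p = 0.191 with an estimated correlation). Flavonoid genes fell in 4 of 9 (4 over the list alone, 0.0469, adjusted p = 0.428 with an estimated correlation), with CHS, which encodes chalcone synthase, at -0.88 ± 0.16. Brassinosteroid and gibberellin genes rose in 6 of 11 and fell in 2 (7 and 2 over the list alone, 0.0477, adjusted p = 0.436 with an estimated correlation), with the gibberellin 20-oxidase gene GA20OX2 at 2.13 ± 0.27.

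Another comparison asked the same of the line with the K962A substitution. The ACC synthase genes ACS5, ACS4 and ACS8 rose by 7.19 ± 0.27, 7.09 ± 0.22 and 6.24 ± 0.51, ACS4 (AT2G22810, chromosome 2, 9717791 to 9719472) from 1.2 to 164 CPM and ACS8 from 5.9 to 435 CPM. NCED5, of the carotenoid cleavage step of abscisic acid synthesis, rose by 6.89 ± 0.29, the growth regulator gene PRE1 by 6.78 ± 0.29, SAUR10 by 6.42 ± 0.25, the lateral root gene PUCHI by 5.68 ± 0.20 and CKX3 by 5.12 ± 0.26. The gibberellin synthesis genes GA20OX2, GA20OX1 and GA3OX1 rose by 4.43 ± 0.26, 4.27 ± 0.16 and 3.88 ± 0.20. MYB28, a regulator of aliphatic glucosinolate synthesis (-4.43 ± 0.29), the B-box gene BBX14 (-4.18 ± 0.14, from 107 to 5.9 CPM), the xylosidase gene XYL4 (-4.16 ± 0.14) and the GATA factor gene CGA1 (-4.14 ± 0.27) fell. There were 10334 called genes, 4629 higher and 5705 lower, 3559 of them at least 2-fold. The excess of lower genes depended on scaling and filter: edgeR with DESeq2 size factors called 5056 higher and 5133 lower, DESeq2 5201 and 5206, and edgeR with no filter on low counts 4782 and 4777, but with a filter of 10 CPM in 4 libraries 2886 and 3685. Adjusted p-values were 1.2e-16 for ACS5, 2.4e-17 for ACS4 and 3.5e-17 for BBX14 (edgeR, Benjamini-Hochberg).

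In the K962A line all 27 canonical genes rose (27 over the list alone, camera adjusted p = 2.2e-24, adjusted p = 0.0599 with an estimated correlation). SAUR genes rose in 38 of 46 and fell in 4 (38 and 5 over the list alone, 1.0e-20, 0.0106 with an estimated correlation). Aux/IAA genes rose in 22 of 28 and fell in 1 (23 and 1 over the list alone, 2.7e-13, adjusted p = 0.0817 with an estimated correlation). All 7 GH3 genes rose (7 over the list alone, 1.3e-06, adjusted p = 0.0881 with an estimated correlation). Lateral root initiation genes rose in 14 of 18 and fell in 2 (14 and 2 over the list alone, 1.1e-07, adjusted p = 0.0599 with an estimated correlation). Of 17 photosynthesis genes 16 fell (16 over the list alone, 0.000766, adjusted p = 0.384 with an estimated correlation), among them the chlorophyll-binding protein gene LHCB2.2 (-1.49 ± 0.31) and the Rubisco small subunit gene RBCS1B (-1.18 ± 0.16); members of both families may share reads. The plastid share of counts was 28.2 to 34.9% in these 4 libraries and 32.4 to 37.4% in the 4 of K962A mock. Brassinosteroid and gibberellin genes rose in 8 of 11 and fell in 3 (8 and 3 over the list alone, camera adjusted p = 0.00310, adjusted p = 0.232 with an estimated correlation). Expansin and XTH genes rose in 12 of 23 and fell in 7 (12 and 7 over the list alone, 0.0107, adjusted p = 0.228 with an estimated correlation), with EXPA10 at 2.82 ± 0.16. Auxin transport genes rose in 12 of 20 and fell in 5 (12 and 5 over the list alone, 0.0107, adjusted p = 0.0881 with an estimated correlation). Auxin synthesis and oxidation genes fell in 11 of 16 and rose in 3 (11 and 3 over the list alone, 0.00995, adjusted p = 0.126 with an estimated correlation). Root hair genes fell in 6 of 8 (6 over the list alone, 0.00995, adjusted p = 0.158 with an estimated correlation). Defence and jasmonate genes rose in 11 of 20 and fell in 2 (11 and 2 over the list alone, 0.00995, adjusted p = 0.316 with an estimated correlation). Heat genes rose in 5 of 7 (5 over the list alone, 0.0131, adjusted p = 0.316 with an estimated correlation), with DREB2A at 1.71 ± 0.15. Ethylene genes were divided, 10 of 20 higher and 7 lower (10 and 7 over the list alone, camera adjusted p = 0.0596). Cytokinin genes were divided too, 4 of 15 higher and 6 lower (4 and 6 over the list alone, 0.921, median -0.25 and mean -0.12 with the test upward).

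**Figure D3:**
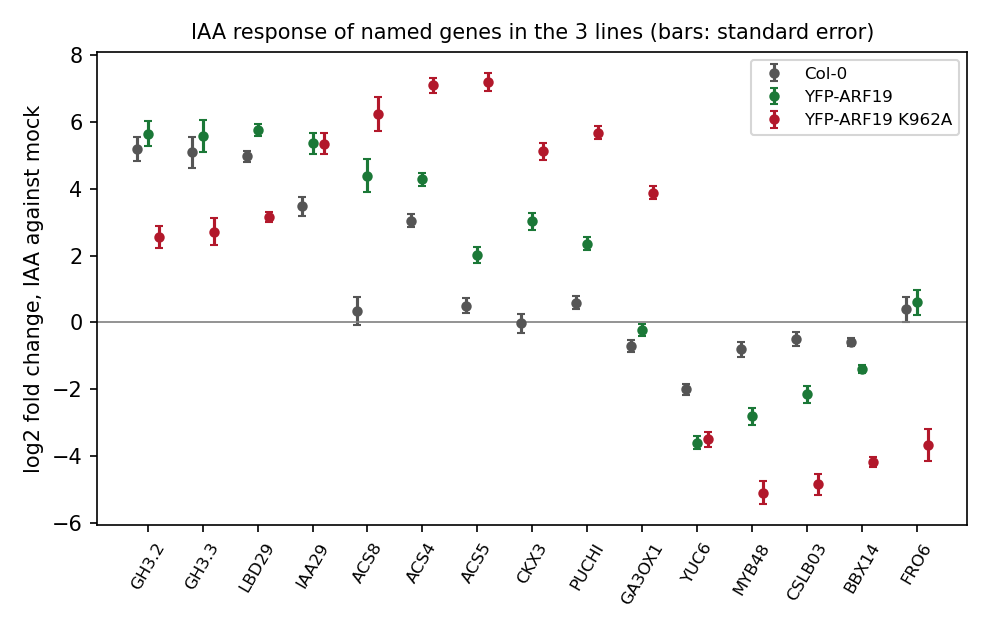
Log2 fold change with IAA (points, with standard errors as bars) of 15 genes in Col-0, YFP-ARF19 and YFP-ARF19 K962A seedlings, 4 libraries per group. ACS5 lies at 0.50, 2.03 and 7.19 and GH3.2 at 5.19, 5.65 and 2.55 in the 3 lines.

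The mean log2 CPM of the 27 canonical genes gave 1 value per library. It rose with IAA by 2.90 ± 0.05 in Col-0, 3.86 ± 0.09 in the YFP-ARF19 line and 3.46 ± 0.36 in the K962A line (SE, n = 4 per group; exact two-sided permutation p = 0.0286 in each, the smallest that 70 relabellings allow). The Benjamini-Hochberg adjusted p over 12 tests was 0.0429 in each. The rise was 0.96 ± 0.10 larger in the YFP-ARF19 line than in Col-0 (permutation p = 0.00367, adjusted p = 0.0429, 4900 relabellings with a smallest p of 0.000408). The rise in the K962A line differed by 0.55 ± 0.37 from Col-0 and by -0.40 ± 0.37 from the YFP-ARF19 line (exact two-sided permutation p = 0.449 and 0.540). The permutation cannot decide these differences: the mean K962A score was above that of Col-0 by 0.99 in mock and 1.54 with IAA, and above that of YFP-ARF19 in both. Exchanging lines within 1 treatment adds these differences where the response subtracts them. With IAA the score itself was higher than in Col-0 by 0.85 ± 0.06 in the YFP-ARF19 line and by 1.54 ± 0.05 in the K962A line, and higher in the K962A line than in the YFP-ARF19 line by 0.69 ± 0.08 (exact two-sided permutation p = 0.0286 each, adjusted 0.0429).

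**Figure D4:**
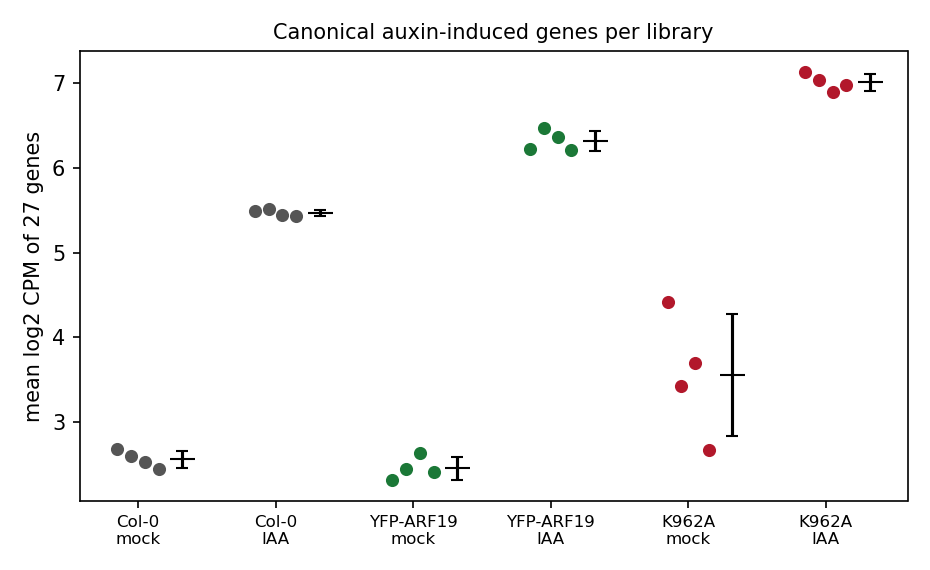
Mean log2 CPM of 27 canonical auxin-induced genes in each library, by line and treatment, with group means and SDs. Col-0 rose from 2.56 to 5.47, YFP-ARF19 from 2.45 to 6.32 and YFP-ARF19 K962A from 3.55 to 7.01, and the 4 K962A mock libraries span 2.67 to 4.42.

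Mock-treated seedlings were compared to ask what the transgenes changed without added auxin. In the YFP-ARF19 line few genes besides ARF19 differed from Col-0: AT5G24240 (chromosome 5, 8230942 to 8234150) was higher by 4.03 ± 0.15, from 1.5 to 24.3 CPM, AT5G35935 by 2.43 ± 0.20, and ARP9, which encodes an actin-related protein, by 0.97 ± 0.10. Genes lower than in Col-0 included AT3G47510 (-2.02 ± 0.27, with adjusted p = 0.0612 when only the groups of the contrast were fitted), AT5G62280 (-1.46 ± 0.26, with adjusted p = 0.0650 and 0.0614 without YFP-ARF19 mock replicate 1 or 2), the aquaporin gene TIP2-3 (-1.13 ± 0.18) and the auxin synthesis gene YUC2, which was 2.01-fold lower. There were 46 called genes, 7 higher and 39 lower, 25 of them at least 2-fold. Adjusted p-values were 5.1e-16 for AT5G24240, 0.00281 for YUC2 and 0.00247 for TIP2-3 (edgeR, Benjamini-Hochberg). DESeq2 called 131, and the count fell to 23 without YFP-ARF19 mock replicate 2, 25 without replicate 1 and 30 without replicate 3 of that group, and 27 without Col-0 mock replicate 1. The nuclear ribosomal RNA share of counts was 1.11 ± 0.763% in YFP-ARF19 mock and 0.559 ± 0.943% in Col-0 mock, against 0.00932 ± 0.00614% in K962A mock (SD, n = 4).

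No canonical gene was called by edgeR over all genes in YFP-ARF19 mock against Col-0, while 2 of 27 were lower over the list alone (camera adjusted p = 0.423). In the whole comparison 2185 of all tested genes had an unadjusted p under 0.05 in edgeR. IAA2 was at -0.48 ± 0.14 and GH3.3 at -0.39 ± 0.39, neither called. The difference in the score of these genes, -0.11 ± 0.08, did not pass (exact two-sided permutation p = 0.257, adjusted 0.309). SAUR genes were lower in 2 of 46 (9 over the list alone, camera adjusted p = 1.1e-08, adjusted p = 0.143 with an estimated correlation), with SAUR68 at -2.54 ± 0.47 (0.0964 against 0.698 CPM). That call was lost under 4 of 14 alternatives, namely without YFP-ARF19 mock replicate 1 (adjusted p = 0.0891) or 2 (0.0614), without Col-0 mock replicate 3 (0.0504) and without the libraries under 20 M counts (0.066). Ethylene genes were lower in 1 of 20 (3 over the list alone, 6.7e-07, adjusted p = 0.143 with an estimated correlation). Genes of auxin synthesis and oxidation were lower in 1 of 16 (4 over the list alone, 0.0141, adjusted p = 0.196 with an estimated correlation). ARF and receptor genes had a median of 0.16 and no called member (none over the list alone, 7.9e-05, adjusted p = 0.196 with an estimated correlation), with ARF7 at 0.35 ± 0.15.

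K962A seedlings in mock were then set against Col-0 in mock. GH3.2, GH3.3 and GH3.5 were higher by 3.59 ± 0.34, 3.12 ± 0.42 and 2.67 ± 0.25, GH3.3 at 561 CPM against 64.8, and the lateral root genes LBD16, LBD18 and LBD17 by 2.64 ± 0.17, 2.39 ± 0.21 and 2.32 ± 0.23. The gibberellin 20-oxidase gene GA20OX5 (5.65 ± 0.39), the peroxidase gene PRX52 (4.83 ± 0.41) and GL2, an epidermal cell fate gene (2.06 ± 0.14), were also higher. TIP2-3 (AT5G47450, chromosome 5, 19248249 to 19249504) was lower at -6.38 ± 0.25, from 14.5 to 0.2 CPM. Also lower were MLP329 (-5.73 ± 0.24), the glutamate receptor gene GLR2.3 (-5.43 ± 0.22), PIN5 (-4.11 ± 0.45), CKX4 (-3.52 ± 0.34), YUC2 (-3.09 ± 0.18), ACS5 (-3.02 ± 0.32) and GA3OX1 (-2.03 ± 0.20). There were 7918 called genes, 3851 higher and 4067 lower, 2497 of them at least 2-fold. Among genes with at least 10 CPM in 4 libraries the balance turned, with 2523 higher and 2282 lower. With only the groups of the contrast fitted, 5648 were called, 2391 higher and 3257 lower. The main fit shares the dispersion of each gene among all groups, while K962A mock libraries were spread more widely in auxin-induced transcripts. P-values of comparisons with this group may therefore be too small, and those of auxin-induced genes in comparisons without it too large. Adjusted p-values were 3.2e-08 for GH3.2, 1.4e-11 for LBD16 and 9.7e-16 for TIP2-3 (edgeR, Benjamini-Hochberg).

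Of the canonical genes 18 of 27 were higher in K962A mock than in Col-0 mock and 2 lower (18 and 2 over the list alone, camera adjusted p = 9.9e-06, adjusted p = 0.374 with an estimated correlation). The score differed by 0.99 ± 0.36, which missed the threshold (exact two-sided permutation p = 0.0571, adjusted 0.0762) with the spread of 2.67 to 4.42 in the K962A mock libraries. Without K962A mock replicate 4 it was 1.27 (exact permutation p = 0.0286), and without replicate 1, the library with the highest score, 0.70 (exact permutation p = 0.0571). All 7 GH3 genes were higher (7 over the list alone, 4.1e-05, adjusted p = 0.215 with an estimated correlation). Lateral root initiation genes were higher in 12 of 18 and lower in 3 (12 and 3 over the list alone, 0.000117, adjusted p = 0.192 with an estimated correlation). SAUR genes were lower in 22 of 46 and higher in 7 (23 and 7 over the list alone, 0.000691, adjusted p = 0.291 with an estimated correlation), with SAUR55 at 2.08 ± 0.19 and SAUR68 at -2.64 ± 0.42. ARF and receptor genes were higher in 9 of 20 and lower in 1 (10 and 1 over the list alone, 0.00273, adjusted p = 0.291 with an estimated correlation), with ARF10 at 1.58 ± 0.14. Cytokinin genes were lower in 10 of 15 (10 over the list alone, 0.000174, adjusted p = 0.192 with an estimated correlation). Auxin synthesis and oxidation genes were lower in 8 of 16 and higher in 2 (8 and 2 over the list alone, 0.000613, adjusted p = 0.192 with an estimated correlation). Cell cycle genes were lower in 11 of 14 (11 over the list alone, 0.000691, adjusted p = 0.290 with an estimated correlation), with the mitotic cyclin gene CYCB1;4 at -1.10 ± 0.16 and the cytokinesis syntaxin gene KNOLLE at -0.97 ± 0.18. Flavonoid genes were lower in 6 of 9 (6 over the list alone, 0.00132, adjusted p = 0.283 with an estimated correlation), with FLS1 at -1.61 ± 0.17 and CHI at -1.47 ± 0.17. Photosynthesis genes were lower in 8 of 17 (11 over the list alone, 0.00176, adjusted p = 0.527 with an estimated correlation). Circadian genes were higher in 6 of 13 (7 over the list alone, 0.0161, adjusted p = 0.283 with an estimated correlation). Root markers were divided, 4 of 13 higher and 5 lower (4 and 5 over the list alone, camera adjusted p = 0.735, median 0.11 and mean -0.31).

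K962A mock was also compared with YFP-ARF19 mock, which asks what the substitution itself changed between the transgenic lines. The labels name 1 line per construct, so substitution and line cannot be told apart. GH3.2, GH3.3 and GH3.5 were higher by 3.55 ± 0.34, 3.51 ± 0.43 and 2.73 ± 0.25, LBD18, LBD17 and LBD16 by 2.69 ± 0.22, 2.47 ± 0.24 and 2.47 ± 0.17, and the plastid transporter gene GPT2 by 4.21 ± 0.43. MLP329 (-5.61 ± 0.24), TIP2-3 (-5.25 ± 0.26), PIN5 (-4.24 ± 0.45), CKX4 (-3.70 ± 0.34) and the cell wall gene XTH33 (-2.94 ± 0.30) were lower. There were 6740 called genes, 3439 higher and 3301 lower, 2215 of them at least 2-fold. This balance turned with DESeq2 size factors in edgeR (3208 higher and 3445 lower), with DESeq2 (3379 and 3583), without organelle and ribosomal RNA genes (3265 and 3403) and with only the groups of the contrast (2590 and 3282), while a filter of 10 CPM in 4 libraries gave 2220 and 1808. Adjusted p-values were 4.7e-08 for GH3.2 and 1.4e-09 for LBD18 (edgeR, Benjamini-Hochberg). The canonical score was 2.14-fold higher with an SE of 0.37 on the log2 scale (exact two-sided permutation p = 0.0286, adjusted 0.0429). That call ended without the libraries under 20 M counts (1.16, exact permutation p = 0.0571) and with a prior count of 0.5 (1.09, exact permutation p = 0.0571). It also ended without any 1 of the YFP-ARF19 mock libraries, though the difference stayed at 1.05 to 1.16 (exact permutation p = 0.0571 each). The lowest K962A mock score (2.67) lay above the highest YFP-ARF19 mock score (2.63). That library, K962A mock replicate 4, lay below the highest Col-0 mock score (2.68, replicate 1).

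In that comparison 18 of 27 canonical genes were higher and 1 lower (20 and 1 over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.323 with an estimated correlation). GH3 genes were higher in 6 of 7 (6 over the list alone, 3.1e-05, adjusted p = 0.188 with an estimated correlation). Aux/IAA genes were higher in 13 of 28 and lower in 2 (16 and 2 over the list alone, 0.0231, adjusted p = 0.624 with an estimated correlation). Lateral root initiation genes were higher in 11 of 18 and lower in 3 (12 and 4 over the list alone, 0.000258, adjusted p = 0.188 with an estimated correlation). Ethylene genes were higher in 12 of 20 and lower in 3 (13 and 3 over the list alone, 0.00294, adjusted p = 0.323 with an estimated correlation), with ACS11 at 2.04 ± 0.27 and ACS4 at -1.19 ± 0.23. Cytokinin genes were lower in 11 of 15 (11 over the list alone, 4.0e-05, adjusted p = 0.188 with an estimated correlation). Flavonoid genes were lower in 6 of 9 (7 over the list alone, 0.000258, adjusted p = 0.188 with an estimated correlation). Cell cycle genes were lower in 10 of 14 (11 over the list alone, 0.00145, adjusted p = 0.323 with an estimated correlation). Photosynthesis genes were lower in 1 of 17 (none over the list alone, 0.0251, adjusted p = 0.664 with an estimated correlation). Genes of auxin synthesis and oxidation were lower in 6 of 16 and higher in 2 (6 and 2 over the list alone, 0.00454, adjusted p = 0.188 with an estimated correlation). Defence and jasmonate genes were higher in 9 of 20 and lower in 2 (10 and 3 over the list alone, 0.0258, adjusted p = 0.512 with an estimated correlation), with CYP81F2, of indole glucosinolate modification, at 1.96 ± 0.27.

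The mock differences were also read along the IAA response, with the response taken from the line that was not part of the comparison. Of 3644 genes that rose with IAA in the YFP-ARF19 line, 71.0% were higher in K962A mock than in Col-0 mock, and of 3176 that fell 73.3% were lower, where 53.0% of all tested genes were higher. The median log2 difference was 0.217 for the genes that rose and -0.326 for those that fell. The score of these genes was higher by 0.81 ± 0.14 (exact two-sided permutation p = 0.0286). In size, the score differences along the IAA response fit the mean of genes that rose less that of genes that fell. They are thus not on the scale of the common response score. Of 3147 genes that rose with IAA in Col-0, 78.1% were higher in K962A mock than in YFP-ARF19 mock, and of 2715 that fell 74.2% were lower, where 54.0% of all tested genes were higher (score difference 0.82 ± 0.12, exact two-sided permutation p = 0.0286). For YFP-ARF19 against Col-0 in mock, with the 4629 and 5705 genes called in the K962A line, the shares were 35.3% higher and 44.2% lower, where 46.7% of all tested genes were higher, and the score difference of -0.09 ± 0.05 did not pass (exact permutation p = 0.114). Between the genes called against Col-0 in mock in the YFP-ARF19 line (46) and the K962A line (7918), 27 went the same way and 4 opposite ways. Independent lists of these sizes would share 1.22 higher and 7.19 lower. Simulated unchanged groups against the same controls shared 0, but they hold no true change to call, so this is no reference for the 27. Each comparison was also given its own pair of Col-0 mock libraries. In the first division 28 genes were shared of 81 and 6641 called, and in the other 16 of 22 and 6404. The fold changes of the 2 comparisons correlated across genes at 0.24, and at 0.0331 and 0.0768 with divided Col-0 libraries. The simulated groups gave 0.51, which comes from the shared controls alone and is no reference where true changes are present. The covariance was 0.0581 against 0.0260 in the simulated groups. Genes are not independent replicates.

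The differences between the IAA responses addressed whether the lines responded alike. The response was larger in the YFP-ARF19 line than in Col-0 for ACS8 by 4.04 ± 0.64, for CKX3 by 3.05 ± 0.39, for ACS9 by 2.92 ± 0.56, for the transcription factor gene NAC2 (AT3G15510) by 2.21 ± 0.20, for IAA29 (AT4G32280, chromosome 4, 15583387 to 15584769) by 1.89 ± 0.39 and for PUCHI by 1.76 ± 0.26. It was more negative for MYB48 (-2.01 ± 0.33), YUC8 (-1.74 ± 0.27), the transporter gene ABCG14 (-1.69 ± 0.29) and YUC6 (-1.60 ± 0.26). GH3.3 and GH3.2 differed by 0.49 ± 0.55 and 0.46 ± 0.44, neither called. The shared dispersion takes in the wide spread of K962A mock in auxin-induced transcripts. A missed call of such a gene here therefore does not show that the responses were alike. There were 210 called genes, 130 with a positive and 80 with a negative difference. Adjusted p-values were 0.00236 for ACS8, 6.3e-07 for NAC2 and 0.0147 for IAA29 (edgeR, Benjamini-Hochberg). DESeq2 called 383, and edgeR fitted to the 4 groups of the comparison alone called 336.

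Ethylene genes had a larger response in the YFP-ARF19 line in 4 of 20 (7 over the list alone, camera adjusted p = 1.4e-10, 0.0328 with an estimated correlation). SAUR genes had a larger response in 7 of 46 (20 over the list alone, 4.8e-12, 0.0375 with an estimated correlation). Auxin synthesis and oxidation genes had a more negative response in 4 of 16 (6 over the list alone, 3.2e-05, 0.0328 with an estimated correlation). Canonical genes had a larger response in 5 of 27 (16 over the list alone, 4.8e-19, adjusted p = 0.0676 with an estimated correlation). Aux/IAA genes had a larger response in 3 of 28 (10, with 1 more negative, over the list alone, 3.6e-12, adjusted p = 0.0676 with an estimated correlation). Lateral root initiation genes had a larger response in 3 of 18 (7 over the list alone, 1.1e-06, adjusted p = 0.0528 with an estimated correlation). The GH3 list had a larger response with no called member (2 over the list alone, 0.0264, adjusted p = 0.484 with an estimated correlation). So had the defence and jasmonate list (none over the list alone, 0.00416, adjusted p = 0.362 with an estimated correlation) and the cell cycle list (none over the list alone, 0.0350, adjusted p = 0.484 with an estimated correlation). Brassinosteroid and gibberellin genes had 1 called member of 11, GA20OX1 at 1.21 ± 0.21 (2 over the list alone, 0.00440, adjusted p = 0.362 with an estimated correlation).

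Against Col-0, the K962A line had a larger response for ACS5 by 6.69 ± 0.37, ACS8 by 5.90 ± 0.64, CKX3 by 5.14 ± 0.38, PUCHI by 5.08 ± 0.27, GA3OX1 (AT1G15550, chromosome 1, 5344478 to 5346166) by 4.59 ± 0.27, the potassium channel gene KAT1 by 4.26 ± 0.21 and ACS4 by 4.04 ± 0.27. It was more negative for the cellulose synthase-like gene CSLB03 (-4.35 ± 0.41), MYB48 (-4.28 ± 0.42), the ferric reductase gene FRO6 (-4.05 ± 0.61), BBX14 (-3.61 ± 0.18), CGA1 (-3.58 ± 0.36), GH3.2 (-2.64 ± 0.44), GH3.3 (-2.38 ± 0.55), LBD29 (-1.82 ± 0.23) and LBD16 (-1.69 ± 0.22). FRO6 and FRO7 are neighbouring copies that may share reads. GH3.2, GH3.3 and LBD16 were among the genes already higher in K962A mock, and with IAA GH3.3 reached 3686 CPM in the K962A line and 2208 in Col-0. ACS5 and GA3OX1 were among the genes lower in K962A mock than in Col-0 mock, which is part of their larger response. There were 4020 called genes, 1667 with a positive and 2353 with a negative difference; with DESeq2 size factors in edgeR the numbers were 1846 and 2071, with DESeq2 2036 and 2239, and with a filter of 10 CPM in 4 libraries 999 and 1667. Adjusted p-values were 2.2e-12 for ACS5, 1.6e-12 for PUCHI and 0.000128 for GH3.2 (edgeR, Benjamini-Hochberg).

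SAUR genes had a larger response in the K962A line than in Col-0 in 35 of 46 and a smaller one in 2 (38 and 2 over the list alone, camera adjusted p = 1.1e-22, 0.00630 with an estimated correlation). In mock, 22 of the 46 were lower in the K962A line than in Col-0 and 7 higher. Aux/IAA genes had a larger response in 11 of 28 and a smaller one in 1 (11 and 2 over the list alone, camera adjusted p = 1.4e-05, adjusted p = 0.448 with an estimated correlation). Cytokinin genes had a more positive response in 6 of 15 and a more negative in 3 (8 and 3 over the list alone, 0.00148, adjusted p = 0.291 with an estimated correlation). Brassinosteroid and gibberellin genes were more positive in 6 of 11 and more negative in 2 (6 and 2 over the list alone, 0.000614, adjusted p = 0.313 with an estimated correlation). Expansin and XTH genes were more positive in 8 of 23 and more negative in 3 (8 and 3 over the list alone, 0.0357, adjusted p = 0.448 with an estimated correlation). Circadian genes were more negative in 4 of 13 (5 over the list alone, 0.00260, adjusted p = 0.234 with an estimated correlation). Photosynthesis genes were more negative in 4 of 17 (4 over the list alone, 0.00427, adjusted p = 0.748 with an estimated correlation). Canonical genes were divided, 7 of 27 more positive and 5 more negative (7 and 7 over the list alone, 0.0496, adjusted p = 0.845 with an estimated correlation). Ethylene genes were divided with 5 of 20 each way (6 and 9 over the list alone, 0.856, median -0.49 and mean 0.66).

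Against the YFP-ARF19 line, the K962A line had a larger response for MEE3 by 6.02 ± 0.43, ACS5 by 5.16 ± 0.39, GA3OX1 by 4.11 ± 0.27, KAT1 by 4.11 ± 0.21, PUCHI by 3.32 ± 0.26 and ACS4 by 2.81 ± 0.28. It was more negative for FRO6 (-4.27 ± 0.61), GH3.2 (-3.10 ± 0.44), XYL4 (-2.94 ± 0.17), GH3.3 (-2.87 ± 0.56) and LBD29 (-2.62 ± 0.23). GH3.2 and GH3.3 were already higher in K962A mock than in YFP-ARF19 mock, which is part of their smaller response. With IAA, GH3.3 was at 2361 CPM in the YFP-ARF19 line, less than in the K962A line. There were 3728 called genes, 1496 with a positive and 2232 with a negative difference. The excess of negative ones depended on scaling and filter, with 1700 and 1770 for DESeq2 size factors in edgeR, 1946 and 1999 for DESeq2, and 1466 and 1527 for edgeR with no filter on low counts, but 941 and 1747 with a filter of 10 CPM in 4 libraries. Adjusted p-values were 9.9e-10 for MEE3, 1.3e-09 for ACS5 and 3.2e-05 for GH3.2 (edgeR, Benjamini-Hochberg). SAUR genes had a larger response in 27 of 46 and a smaller one in 2 (33 and 3 over the list alone, camera adjusted p = 2.3e-13, adjusted p = 0.0659 with an estimated correlation). Cytokinin genes had a more positive response in 7 of 15 and a more negative in 2 (7 and 3 over the list alone, 0.00112, adjusted p = 0.349 with an estimated correlation). Photosynthesis genes had a more negative response in 9 of 17 (16 over the list alone, 8.3e-05, adjusted p = 0.398 with an estimated correlation). Brassinosteroid and gibberellin genes were more positive in 3 of 11 and more negative in 2 (3 and 2 over the list alone, 0.0120, adjusted p = 0.398 with an estimated correlation). Expansin and XTH genes were more positive in 8 of 23 and more negative in 2 (8 and 3 over the list alone, 0.0111, adjusted p = 0.349 with an estimated correlation). Root hair genes were more positive in 4 of 8 and more negative in 1 (4 and 1 over the list alone, 0.0469, adjusted p = 0.398 with an estimated correlation). Flavonoid genes were more positive in 4 of 9 and more negative in 1 (4 and 1 over the list alone, 0.0210, adjusted p = 0.398 with an estimated correlation). Circadian genes were more negative in 4 of 13 (4 over the list alone, 0.0204, adjusted p = 0.349 with an estimated correlation). Of the canonical genes 12 of 27 were more negative and 3 more positive (12 and 4 over the list alone, 0.0524).

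**Figure D5:**
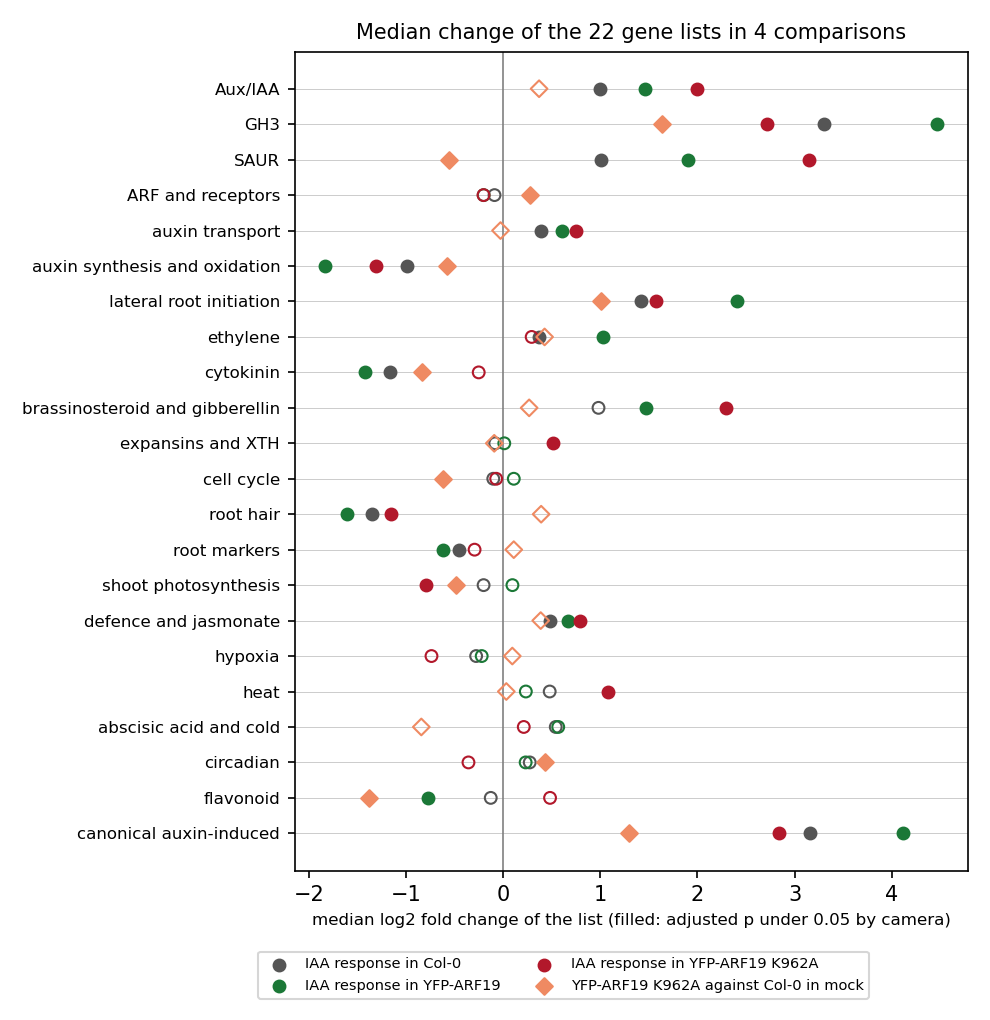
Median log2 fold change of each of the 22 gene lists with IAA in Col-0, YFP-ARF19 and YFP-ARF19 K962A (circles) and in K962A mock against Col-0 mock (diamonds), filled where camera with a preset correlation gave an adjusted p under 0.05. SAUR genes lie at 1.01, 1.91, 3.15 and -0.56 and canonical auxin-induced genes at 3.16, 4.11, 2.84 and 1.29.

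Calls with IAA overlapped between lines in 4690 genes of the same direction for Col-0 and YFP-ARF19 (12 opposite; 520 higher and 391 lower for independent lists), 4086 for Col-0 and K962A (267 opposite; 661 and 702) and 4826 for the transgenic lines (231 opposite; 765 and 822). All 3 lines called 3584 genes in the same direction, 2087 higher and 1497 lower. Of 4648 genes called in the K962A line and in neither other line, 1451 also differed from Col-0 by the test of the difference and 1020 from both. A common response of 2655 genes, chosen on the mean effect over the 3 lines and with 1468 higher and 1187 lower, had median changes in its direction of 1.36 in Col-0, 1.68 in YFP-ARF19 and 1.66 in K962A. Its score rose by 0.33 ± 0.06 more in YFP-ARF19 than in Col-0 (permutation p = 0.00490, adjusted p = 0.0381 over 12 tests). For K962A the differences were 0.29 ± 0.13 from Col-0 and -0.04 ± 0.12 from YFP-ARF19 (exact two-sided permutation p = 0.514 and 0.941). The permutation cannot decide these either, since the K962A score was higher than that of Col-0 by 0.595 in mock and 0.887 with IAA. It was higher than that of YFP-ARF19 by 0.648 and 0.609. Of the 210 genes that differed between YFP-ARF19 and Col-0, 164 were also called in the same direction for K962A and 7 in the opposite one. Independent lists would share 9.83 and 8.54. Simulated unchanged groups shared 0, but they hold no true change to call, so this is no reference for the 164. With divided Col-0 libraries 110 genes were shared of 237 and 3757 called, and 46 of 64 and 2856. The covariance of the fold changes was 0.141 against 0.0501 simulated. Their correlation across genes was 0.41, or 0.0663 and 0.204 with divided Col-0 libraries. The simulated 0.50 comes from the shared controls alone and is no reference either.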

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

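The tests chosen only after the result was seen were those of endogenous ARF19 induction, of the UBQ10 promoter in the K962A line, of RNA from IAA-treated seedlings in the mock libraries, and of K962A mock replicate 1; the remaining tests here were set before the data were examined.

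Among 108 groups of 4 libraries, over 18 quantities, 5 values, from 4 libraries, stood far from the other 3 of their group by Dixon's test, where chance flags about 1 in 20 groups and so 5.4 here. UBQ10, named outside the naming rule because its promoter drives the transgenes, had 1851 CPM in K962A IAA replicate 3 against 2295 to 2339 in the others. IAA29 had 70.4 CPM in Col-0 IAA replicate 3 against 77.9 to 79.0, and TIP2-3 had 4.38 CPM in Col-0 IAA replicate 1 against 3.12 to 3.22. Col-0 mock replicate 1 stood apart in total counts (15.0 M against 36.4 to 38.9 M) and in its share of nuclear ribosomal RNA (1.97% against 0.00700 to 0.136%).

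The IAA response differed between YFP-ARF19 and Col-0 in 210 genes and 10 gene lists (3 with an estimated correlation), in ARF19 (by 1.12 on the log2 scale), in the canonical score (0.96) and in the common score (0.33), with, among genes that meet the naming rule, the most positive difference in ACS8 (4.04) and the most negative in AT1G31050 (-2.03), a call lost under 5 of 24 alternatives. Between K962A and Col-0 it differed in 4020 genes and 8 lists (1 with an estimated correlation), with ACS5 at 6.69 and CSLB03 at -4.35. Between K962A and YFP-ARF19 it differed in 3728 genes and 8 lists (0 with an estimated correlation) and in ARF19 (-0.70), with MEE3 at 6.02 and FRO6 at -4.27.

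The transcriptome of K962A mock differed from that of Col-0 mock in 7918 genes. A smaller share of root tissue alone would lower all root markers alike, but 4 were higher and 5 lower, and the SD of their log2 changes was 2.1. In Col-0, however, 8 of 13 root markers fell within 2 h of IAA, so these genes also respond to auxin. The markers therefore cannot exclude a smaller share of root tissue combined with such regulation. Without plastid, mitochondrial and ribosomal RNA genes 7823 were called, and with all libraries thinned to 15.0 M counts 6743, so neither library composition nor depth accounts for the difference as a whole. A biological effect of the transgene stays open, and so does any other difference of this 1 line from Col-0, such as the place of the insertion, which the design does not separate from the substitution.

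ARF19 reads rose with IAA in both transgenic lines. Induction of the endogenous gene as in Col-0 falls short, since the rise in CPM was 58.5 times that of Col-0 in the K962A line and 85.7 times in the YFP-ARF19 line. UBQ10 itself rose with IAA, but by less than ARF19 reads: the excess of ARF19 was 0.83 (SE 0.18) on the log2 scale in the YFP-ARF19 line and 0.38 (SE 0.18) in the K962A line. The K962A excess is not large against its SE. The low UBQ10 value of K962A IAA replicate 3 (1851 CPM against 2295 to 2339) also lowers the UBQ10 rise there. Library scaling left the rise in the YFP-ARF19 line at 1.66 or more over 3 scalings. Higher activity of the UBQ10 promoter may account for part of the rise, and a change in the stability of the transcript was not tested. In mock, UBQ10 was higher in K962A than in YFP-ARF19 by 0.63 (SE 0.12, edgeR, Benjamini-Hochberg adjusted p = 0.000204). ARF19 reads were higher there by 0.63 (SE 0.13). Against Col-0 mock, UBQ10 differed by 0.54 (SE 0.12) in K962A and by -0.10 (SE 0.12) in YFP-ARF19.

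Of 27 canonical auxin-induced genes 18 were higher in K962A mock than in Col-0 mock by the test per gene and 2 lower. As a list they were not called with an estimated correlation (adjusted p = 0.374), and their score missed the threshold (exact permutation p = 0.0571, adjusted 0.0762). RNA of IAA-treated K962A seedlings in the mock libraries, at the median share of 5.75% that these genes need, would leave every gene at that share of its level with IAA or above. Among genes for which this is at least 1 CPM, 7 lay below 0.5 of the needed level in all 4 libraries, out of 43 whose level in Col-0 mock did not already reach it; ACS4 needed 9.46 CPM and its highest library had 1.80. A bound of 5 CPM was used first and left only 1 such gene, ACS4, too few for the 5 genes the test asked for, and the bound of 1 CPM was chosen after that result, so the outcome depends on this choice. Without K962A mock replicate 1, the library with the highest score, 17 canonical genes were still called higher, so that library alone is not the source. An effect of the protein on auxin-responsive genes without added IAA is a candidate explanation, as is any other difference of this line.

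For each comparison of a pair of groups, 1 of the 35 splits, the real one, called as many genes as the real one. That share is under 0.05 but is the smallest that 35 splits allow. Mixed splits also join differing groups, which widens the spread, and they called a median of 0 genes. The splits therefore do not exclude a chance arrangement of the libraries. The IAA comparisons of different lines share no library, however. Their calls went the same way in 4690 genes and opposite ways in 12 for Col-0 and YFP-ARF19. For K962A the numbers were 4086 and 267 with Col-0, and 4826 and 231 with YFP-ARF19. These values argue against a chance arrangement for the IAA responses and do not bear on the mock comparisons. The real and the highest other count were 5862 and 438 with IAA in Col-0, 6820 and 357 in YFP-ARF19, and 10334 and 338 in K962A. In mock they were 46 and 1 for YFP-ARF19 against Col-0, 7918 and 1421 for K962A against Col-0, and 6740 and 850 for K962A against YFP-ARF19. Among 50 splits for the differences of responses, the counts were 210 and 2 for YFP-ARF19 and Col-0. They were 4020 and 1769 for K962A and Col-0, and in both the real split alone reached its count. These splits can also add line differences shared by both treatments, so they cannot exclude chance. For K962A and YFP-ARF19, 2 of the 50 splits called as many genes as the real split, which called 3728. The other of them called 4897 and points to a structure of the samples. It exchanged all 4 mock libraries between the lines and left 3 of the 4 IAA libraries in place, so that it mostly added the line differences in mock and with IAA.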

How the results depend on the processing

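Leaving out the libraries under 20 M counts was chosen after the data were seen; the other alternatives here were set before the data were examined. No called difference in a named gene, in ARF19 or in a score changed sign under an alternative that was run. The balance of higher and lower calls did turn in K962A mock against YFP-ARF19 mock, from 3439 and 3301 to 3379 and 3583 with DESeq2. It also turned against Col-0 mock with a filter of 10 CPM (2523 and 2282), and with IAA in K962A with no filter (4782 and 4777). DESeq2 size factors in edgeR, DESeq2, and TMM without organelle and ribosomal RNA genes shifted the log2 fold changes by a median of at most 0.0532.

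A filter of 10 CPM in 4 libraries tests 12148 genes in place of 22052, fewer by construction. It called 3875 genes with IAA in Col-0, 4342 in YFP-ARF19 and 6571 in K962A, 4805 and 4028 in K962A mock against Col-0 and YFP-ARF19 mock, and 2666 in the difference of responses between K962A and Col-0.

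YFP-ARF19 against Col-0 in mock, with 46 genes, depended most on the processing. DESeq2 called 131, which included the 46, fitting only the groups of the contrast called 29, and leaving out the libraries under 20 M counts called 23. With each library left out in turn the count ran from 23 (without YFP-ARF19 mock replicate 2) to 66 (without Col-0 mock replicate 4). The cause was not tested. The difference of responses between YFP-ARF19 and Col-0, with 210 genes, became 383 with DESeq2, 209 of them shared, and 336 with only the groups of the contrast, 199 of them shared, and again the cause was not tested.

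The difference in the ARF19 response between K962A and Col-0 ran from 0.35 to 0.55 with each library left out, and passed only without K962A IAA replicate 4 (adjusted p = 0.0491); the cause was not tested. The canonical score in K962A mock against Col-0 mock ran from 0.70 (without K962A mock replicate 1) to 1.27 (without K962A mock replicate 4). Against YFP-ARF19 mock it ran from 0.81 to 1.37. There it missed the threshold with a prior count of 0.5 (1.09), without the libraries under 20 M counts (1.16) and with any YFP-ARF19 mock library left out (1.05 to 1.16). The exact permutation p was 0.0571 each, where 0.0286 is the smallest possible. With a YFP-ARF19 mock library left out the groups are unequal. A relabelling with the highest scores in the smaller group then gives a larger difference than the real labels. For the prior count of 0.5 the cause was not tested.

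With an estimated correlation in place of 0.01, the called lists went from 12 to 4 with IAA in Col-0, 14 to 8 in YFP-ARF19 and 13 to 1 in K962A, from 4, 11 and 11 to 0 in the 3 mock comparisons, and from 10 to 3, 8 to 1 and 8 to 0 in the differences of responses. The lower counts follow from the larger variance that such a correlation gives each list. This correlation was estimated over all 24 libraries, including the widely spread K962A mock ones, and was the same in every contrast. A list not called with it is therefore not shown to be unchanged.

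The replicate block left the calls near their main values, such as 5727 genes with IAA in Col-0 and 3926 in the difference between K962A and Col-0. Among named genes, 667 gene results were repeated under the alternatives, giving 12108 values: 11498 kept direction and call, 610 lost the call and 0 reversed.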

Other observations

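The values below come from the contrasts set before the data were examined, but what to look at was chosen after the values were seen. No explanation is given.

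Genes called with IAA in opposite directions in Col-0 and the K962A line numbered 267. GA3OX1, of gibberellin synthesis, was at -0.71 ± 0.19 in Col-0 and 3.88 ± 0.20 in K962A. The auxin transporter gene PIN5 was at -1.70 ± 0.37 in Col-0 and 1.92 ± 0.50 in K962A, where mock levels differed from Col-0 by -4.11 ± 0.45 on the log2 scale.

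The pathogenesis gene PR1 was at 7.66 CPM in K962A mock and 6.14 with IAA, against 0.0552 and 0.0435 in Col-0. The seed storage protein gene CRA1 was at 16.4 CPM in K962A mock against 0.545 in Col-0 mock (log2 difference 4.78 ± 0.74). MLP34 was at 0.919 CPM in K962A mock against 37.5 in Col-0 mock and 40.4 in YFP-ARF19 mock. In the YFP-ARF19 line AT5G24240 was at 24.3 CPM in mock and 27.8 with IAA, against 1.48 and 1.04 in Col-0.

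The ribosomal RNA gene AT3G41768 was uneven in Col-0 mock, with 20829 CPM in replicate 1 and 70.9, 1325 and 1155 in replicates 2 to 4. In K962A mock it ranged from 46.5 to 185 CPM and in YFP-ARF19 mock from 3663 to 20024.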
